A study of Mus musculus with 6 samples.

How the data were processed

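The samples were pooled mouse embryonic hearts (strain C57BL/6, embryonic day 9.5), 3 pools of Hdac3-flox/flox and 3 of Hdac3-flox/flox; Isl1-Cre (Hdac3-Isl1KO). Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, and biotin-labelled, fragmented cDNA was made from 100 ng of it with the Affymetrix WT PLUS kit, which primes along whole transcripts. How many hearts went into a pool, and whether pools came from separate litters, is not given in the sources used here. P-values therefore measure the spread between these pools, which may be partly technical.

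The authors deposited log2 expression values, and per the submitters' processing notes the tools were oligo and RMA, which corrects background, quantile normalizes arrays and summarises probes on the log2 scale. Their versions, and the genome build and annotation behind the probe sets, are not given in the sources used here. The values ran from 1.43 to 14.2 over the 6 arrays and were used as they stood. No detection calls, scan dates or chip batches were used here, so dim values cannot be separated from background and array batches cannot be tested. RMA compresses differences of dim probe sets, so fold changes of dim genes are understated.

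Array rows were named from the platform annotation. Of 41345 rows, 23521 had 1 gene symbol, 1814 had several and 16010 had none listed. Of the rows with 1 symbol, 23328 were matched by gene number to a RefSeq gene table of assembly GRCm38.p6 and 193 were not, and 0 symbols changed. That table was used only for names, gene types, gene spans and which gene contains a small nucleolar RNA gene, and no coordinates are given because the build of the array annotation is not known. Rows with several symbols or none were left out of the main comparison. For the 1082 genes with several rows, the row with the highest mean over all arrays was used, which left 22180 genes, 18964 of them protein-coding. No filter on dim genes was applied.

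Before averaging, the arrays were compared: the lowest correlation between any pair was 0.980 and none were duplicates. Differences are Hdac3-Isl1KO minus Hdac3-flox/flox on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided, 4 residual degrees of freedom per gene and 6.92 with the prior), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are SDs over 3 arrays or 95% intervals from the fit. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The limma steps were tested on simulated data with the same 22180 genes, 3 arrays per group and 200 changed genes. A log2 change of 1 was recovered for 79% of changed genes with 7 false calls, a change of 0.5 for 23% with 2 false calls, and 0 genes were called with no change. The simulated noise was independent between genes, with spreads shuffled over genes. These rates therefore check the steps and need not hold for the real arrays.

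The gene lists (33 lists naming 694 genes, of which 648 were measured) covered heart progenitor, muscle, signalling, metabolic and cell type genes, including other tissues that dissected hearts can carry along. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with an estimated correlation, limma's fry and camera on ranks as alternatives. Counts called adjusted over the list alone use the same p-values adjusted within each list. The genes named in the text were chosen by a fixed rule: Hdac3, Isl1, Tgfb1, Tgfb2, Tgfb3 and Cdkn1a in any case, the 12 largest rises and 12 largest falls among genes past the threshold, up to 4 members of each list with the smallest p-values, and all sex-linked genes of the lists. Symbols of predicted genes, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes were left out of the largest changes, 19 of the 95 genes, but counted. Members that passed over a list alone, Clca3a2, Nppa and the genes and gene families of the closing section were named after their values were seen. The design, the rule, the lists and the alternatives were fixed before the data were examined, except as stated.

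Alternatives were a replicate block, each array left out in turn, quantile normalization, arrays centred on their medians, leaving out genes below the median or the 25th percentile row, the mean of a gene's rows, a prior trended on the mean level with and without robust estimation, array weights, and other thresholds. A test of protein-coding genes only was added after the data were seen. After the changed genes were seen, lists of trophoblast genes picked for their higher values, other trophoblast markers, parietal endoderm and Reichert's membrane genes and decidual markers were also added, as were lists made by symbol of small nucleolar RNA genes (Snora and Snord followed by a number) and protein-coding ribosomal protein genes (Rpl and Rps). The first held 73 of the measured genes, while 80 measured genes had the type snoRNA in the RefSeq table, some under other symbols. The report gives the number of small nucleolar RNA genes that fell and their comparison with host genes, and all else on these lists is in the closing section.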

Results

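Hdac3 encodes a histone deacetylase that acts in corepressor complexes. Isl1-Cre directs recombination to Isl1-expressing cells, which include the second heart field, the progenitor population that adds the outflow tract and right ventricle to the growing heart tube. Gene expression was measured on Affymetrix arrays in mouse embryonic hearts at embryonic day 9.5. There were 3 samples from Hdac3-flox/flox embryos, which carry the floxed gene without Cre, and 3 from Hdac3-flox/flox; Isl1-Cre embryos, called Hdac3-Isl1KO. Each sample was a pool of hearts. The data were RMA log2 values, and the 23521 array rows that carried 1 gene symbol gave 22180 genes. The median value per array lay between 5.64 and 5.71, and correlations between arrays lay between 0.980 and 0.989. Hdac3-flox/flox replicate 2 had the lowest mean correlation with the other arrays, 0.982, and lay farthest out on the first principal component, at -26.6 against -8.39 and -1.83 for the other Hdac3-flox/flox arrays. The number of arrays limits the precision of all values.

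The comparison asks what changes in the heart when Hdac3 is lost in the second heart field lineage. The controls carried no Cre, so effects of the Isl1-Cre allele itself cannot be told apart from those of Hdac3 loss. Hdac3 itself was lower in the Hdac3-Isl1KO hearts, at 9.21 ± 0.10 (SD, n = 3) against 9.68 ± 0.05 (SD, n = 3) on the log2 scale. The difference was -0.47 (95% interval -0.66 to -0.29), or 1.39-fold lower. The arrays read 9.11, 9.20 and 9.31 in Hdac3-Isl1KO and 9.67, 9.73 and 9.64 in Hdac3-flox/flox, so the groups did not overlap. With limma, the unadjusted p was 0.000481 and the adjusted p over all genes was 0.0636, which missed the threshold of 0.05. The value stayed between -0.52 and -0.43 with any 1 array left out. A variance prior that follows the mean level (limma adjusted p = 0.00111), array weights (0.0419) and leaving out dim genes (0.0109 above the median row, 0.0335 above the 25th percentile) took it past the threshold, and over all settings its limma adjusted p ranged from 0.00108 to 0.244. The tissue was whole heart, in which only part of the cells express Isl1-Cre, and where in the gene the probes lie relative to the floxed part is not known here, so the value checks the labels only in part. Isl1 differed by -0.033 (95% interval -0.27 to 0.20, limma adjusted p = 0.913), and that sign turned under quantile normalization (0.026) and with some arrays left out (range -0.10 to 0.06).

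In the Hdac3-Isl1KO hearts 51 genes rose and 44 fell (limma, adjusted p under 0.05), which is 95 of 22180 genes or 0.428%. Their log2 changes ranged from 0.45 to 1.81 and from -0.44 to -1.96, and 17 genes changed at least 2-fold, 8 upward and 9 downward. The largest rises were placental hormones and steroid synthesis genes. Prl4a1, of the placental prolactin family, rose 3.51-fold, from 5.94 ± 0.01 to 7.75 ± 0.13 (SD, n = 3 each, limma adjusted p = 0.00127). Its relatives Prl3d3 and Prl7a1 rose 2.72-fold and 2.50-fold, and Psg29, a pregnancy-specific glycoprotein, rose 2.32-fold. Cyp11a1 and Star, which carry out the first steps of steroid hormone synthesis from cholesterol, rose 2.54-fold and 2.33-fold. Tdo2, a tryptophan-degrading enzyme, rose 2.30-fold, and A2m, a protease inhibitor, 2.16-fold. Smaller rises were seen for Rpl9 (1.93-fold), a ribosomal protein, Guca2b (1.92-fold), the fibrinogen chain gene Fgb (1.91-fold) and Lama1 (1.85-fold), a laminin of early basement membranes. Limma adjusted p-values of these 12 genes ranged from 0.00127 to 0.0345. The prolactin and Psg families and Rpl9 have close relatives or pseudogenes that probes can read in common, so their values are uncertain. A dimmer row of Cyp11a1 differed by -0.10 and a dimmer row of Rpl9 by -0.09, and Rpl9 missed the threshold when the rows of a gene were averaged (limma adjusted p = 0.0937; range over all settings 1.71e-05 to 0.105).

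With small nucleolar RNA genes and the other symbol classes excluded from naming set aside, the largest falls were in genes of varied function. Clca3a1, of a family of chloride channel regulators, fell from 5.67 ± 0.05 to 3.71 ± 0.13 (SD, n = 3 each), which is 3.90-fold lower (limma adjusted p = 0.00127). Its mean in Hdac3-Isl1KO lay below the 25th percentile of the rows, 4.45, and its close relative Clca3a2 differed by -0.37 (limma adjusted p = 0.504). Tmem255a was 3.20-fold lower, Pkhd1l1 2.16-fold and Erv3 2.13-fold. The uroplakin gene Upk3b was 1.92-fold lower, and Ppbp, a platelet chemokine, 1.90-fold. Aldh1a1, which makes retinoic acid, was 1.86-fold lower, and Hpgd, which breaks down prostaglandins, 1.81-fold. Prl8a2, a prolactin of the decidua, was 1.79-fold lower, opposite in direction to the placental prolactins. The endothelial lipase gene Lipg was 1.78-fold lower, the Kell blood group gene Kel 1.77-fold and the matrix proteoglycan gene Dcn 1.74-fold. The falls also held 13 of 73 measured genes with Snora or Snord symbols, small nucleolar RNA genes whose products guide chemical modification of ribosomal RNA, while 0 of them rose. Several were among the largest falls of all: Snord61, Snord1b and Snord66 were 2.43-fold, 2.33-fold and 2.19-fold lower, more than Pkhd1l1. The gene table's own type for these RNAs held 80 measured genes, of which 13 fell and 0 rose. Without these, 31 genes fell. For the 59 Snora and Snord genes inside 1 measured host gene, a comparison made after their fall was seen, the median was -0.37 against 0.0041 for the hosts over the same pairs, and the host's difference lay above in 53 of 59 pairs. These pairs had 45 different hosts.

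**Figure D1:**
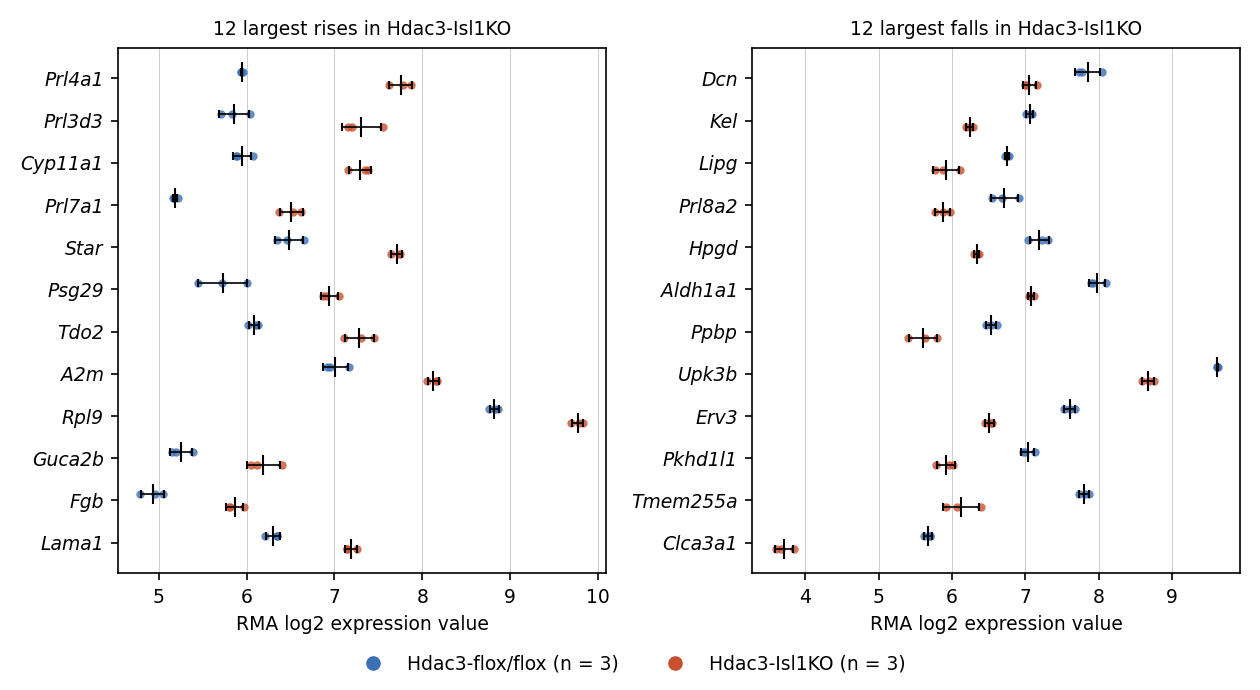
RMA log2 values (horizontal axes) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) among genes past a limma adjusted p of 0.05. Symbols of predicted genes, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes were left out, and some small nucleolar RNA genes fell more than genes shown. Points are single arrays, 3 per genotype (blue Hdac3-flox/flox, red Hdac3-Isl1KO), and bars are the mean ± SD; for Prl4a1 the means are 5.94 and 7.75, and for Clca3a1 5.67 and 3.71.

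**Figure D2:**
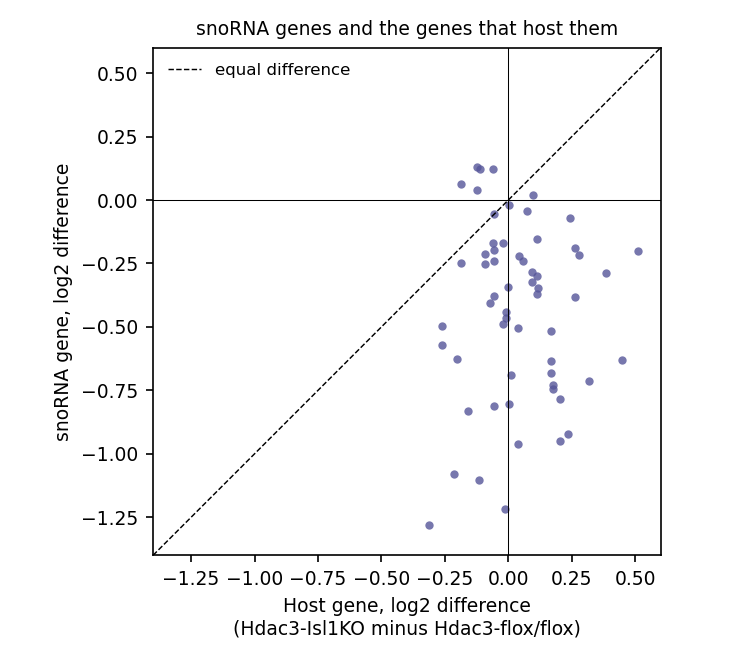
Log2 difference of Hdac3-Isl1KO minus Hdac3-flox/flox for 59 small nucleolar RNA genes (vertical axis) against that of the gene that contains each (horizontal axis). Points are pairs, the dashed line marks equal differences, and in 53 of the 59 pairs, which have 45 different hosts, the difference of the host lies above that of its small nucleolar RNA.

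All 95 genes had non-overlapping groups, as did 4834 of all genes (21.8%, where chance gives 10%), and 3223 genes had an unadjusted limma p under 0.05 where chance gives 1109. The count of 95 rests on every array and on the variance model: it was 6, 25 and 2 without Hdac3-flox/flox replicate 1, 2 or 3, 2, 9 and 5 without Hdac3-Isl1KO replicate 1, 2 or 3, and 866 with a prior that follows the mean level. Quantile normalization gave 149 genes, array weights 243 and leaving out genes below the median row 617, and of the 24 genes above only Prl4a1 and Clca3a1 passed with each array left out in turn, while Upk1b, Cox7a1, Ndufa4, Dlk1, Cdh11, Gja1 and Cpt1a, all list members, missed the threshold with any array left out.

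Of the 33 gene lists, 4 were shifted as a whole by limma's camera test with its preset correlation, 2 up and 2 down, and 0 were with an estimated correlation, where 3 had an unadjusted p under 0.05. Camera on ranks passed 3 lists and fry 5. The list of cardiac calcium handling, ion channel and natriuretic peptide genes was shifted down in Hdac3-Isl1KO. Of 19 measured, 18 had negative differences, with a median of -0.19 (camera adjusted p = 1.00e-05, and adjusted p = 0.0988 with an estimated correlation). Over all genes 1 member fell, the gap junction gene Gja1, by 1.38-fold (limma adjusted p = 0.0410, 0.0562 with arrays centred on their medians, range over all settings 0.000229 to 0.209). Adjusted over the list alone, 5 were lower and 1 higher. The lower ones were Gja1, the other gap junction genes Gja5 and Gjc1 (-0.34 and -0.36), Pln (-0.43), the phospholamban gene that restrains the sarcoplasmic calcium pump, and Kcnj3 (-0.28), a potassium channel gene. The higher one was Nppb (0.39), the gene for brain natriuretic peptide, while Nppa (-0.14), for the atrial peptide, did not pass. The sarcomere genes had 17 of 25 members below 0 and a median of -0.064, with 0 called over all genes and Myoz2 (-0.55) and Myl2 (-0.29) lower when adjusted over the list alone. That list missed the threshold (camera adjusted p = 0.0885) but passed under quantile normalization (0.0147) and with limma's fry (0.00466).

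Markers of the epicardium and of the proepicardium, the cell cluster from which it forms, were also shifted down. Of 15 measured, 11 had negative differences, with a median of -0.13 (camera adjusted p = 0.00159, adjusted p = 0.389 with an estimated correlation, and 0.0630 with camera on ranks, range over all settings 0.000897 to 0.389). The median moved to -0.20 without Hdac3-flox/flox replicate 3 and to -0.083 without Hdac3-Isl1KO replicate 3. Over all genes 3 fell, Upk3b, Upk1b (1.64-fold lower) and Aldh1a1, with limma adjusted p-values from 0.00895 to 0.0268. Adjusted over the list alone 5 fell, the others being Aldh1a2 (-0.66), the main retinoic acid enzyme of the early embryo, and Sema3d (-0.36). Tbx18 and Tcf21, transcription factors of the same cells, both differed by -0.19 and did not pass. Aldh1a1 and Aldh1a2 also belong to the retinoic acid pathway list, of which 1 member fell over all genes, and Crabp2 (0.57) was higher and both aldehyde dehydrogenase genes lower over that list alone. That list as a whole was not shifted (17 measured, median -0.015, camera adjusted p = 0.884).

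Both lists among the 33 that hold endoderm markers were shifted up in the same hearts. The hepatic and yolk sac endoderm markers had 16 of 18 members above 0 and a median of 0.21 (camera adjusted p = 1.04e-05, and adjusted p = 0.0988 with an estimated correlation). Fgb rose over all genes, and adjusted over the list alone 5 were higher: Fgb, Afp (0.84), Alb (0.71), Spink1 (0.57) and Apoa2 (0.39). Alb stood at 4.49 ± 0.21 and 5.19 ± 0.21 and Afp at 6.19 ± 0.15 and 7.03 ± 0.19 in Hdac3-flox/flox and Hdac3-Isl1KO (SD, n = 3 each), where the median row was 5.66. The pharyngeal endoderm and epithelial markers had 17 of 20 members above 0 and a median of 0.17 (camera adjusted p = 2.77e-05, and adjusted p = 0.204 with an estimated correlation). The median was 0.26 without Hdac3-flox/flox replicate 3, and 13 of 20 members were above 0 without Hdac3-flox/flox replicate 2. Over all genes 0 of them passed with limma, 9 had an unadjusted p under 0.05, and adjusted over the list alone 7 were higher: the transcription factor gene Foxa1 (0.32), the adhesion genes Epcam (0.52) and Cdh1 (0.41), the keratin genes Krt8 (0.48) and Krt18 (0.39) and the tight junction genes Cldn6 (0.38) and Cldn7 (0.42). These 7 are largely genes of epithelia in general, so the shift need not mark pharyngeal endoderm. Epcam stood at 4.71 and 5.23 and Cldn6 at 4.93 and 5.31 in Hdac3-flox/flox and Hdac3-Isl1KO, all below the median row. A dimmer row of Krt18 differed by 0.13. The placental genes above moved with both of these lists and opposite to the cardiac and epicardial lists.

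**Figure D3:**
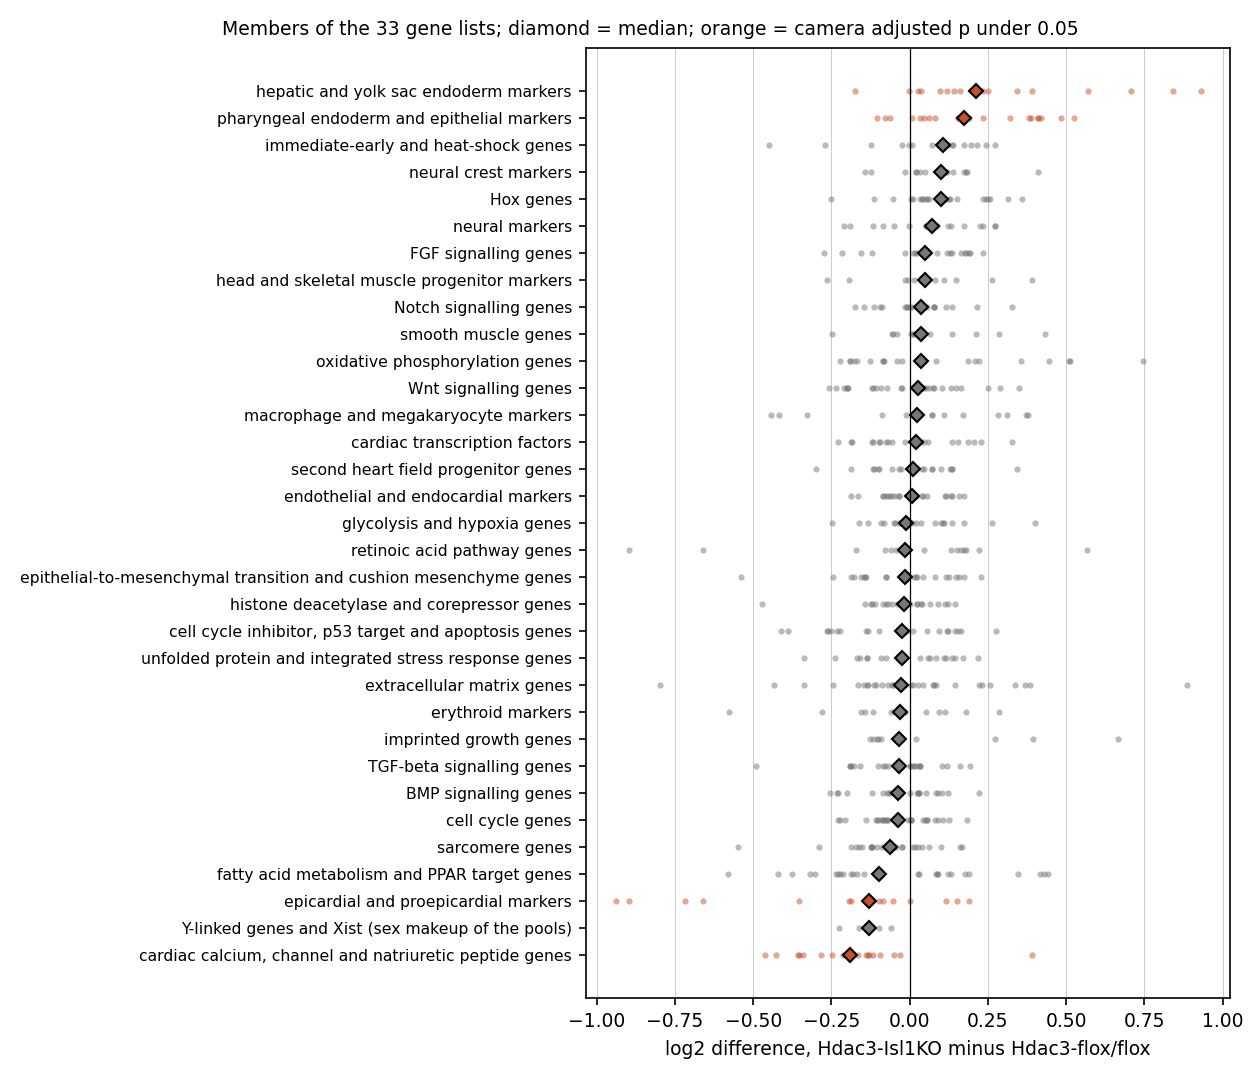
Log2 difference of Hdac3-Isl1KO minus Hdac3-flox/flox (horizontal axis) for the measured members of each of the 33 gene lists. Points are genes, diamonds are list medians, and orange marks the 4 lists past a camera adjusted p of 0.05, with medians of 0.21, 0.17, -0.13 and -0.19.

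The second heart field, cardiac transcription factor, Notch and corepressor lists were not shifted in a common direction. Members that moved both ways would be missed by that test. Second heart field progenitor genes had 10 members above and 10 below 0 (camera adjusted p = 0.996), and 0 passed with limma, over all genes or over the list alone, with 2 at an unadjusted p under 0.05. Osr1 (-0.30), Six2 (0.34), Sema3c (-0.19) and Mef2c (0.14, and -0.070 for a dimmer row) had the smallest p-values. Of 24 cardiac transcription factors 0 passed over all genes, and the Notch target Hey1 (0.33) was higher adjusted over the list alone, while Irx3 (-0.23, and -0.089 for a dimmer row), Tbx5 (-0.18) and Tbx18 did not pass (camera adjusted p = 0.996). Hey1 was also the only member higher over the Notch signalling list alone, where Notch2 (-0.15), Dll1 (-0.18, and -0.036 for a dimmer row) and Hes5 (0.21) did not pass (22 genes, median 0.036, camera adjusted p = 0.555). Of 22 histone deacetylase and corepressor genes Hdac3 alone was lower over the list alone, while Hdac7 (0.15), Hdac9 (-0.12) and Hdac10 (-0.12) did not pass (median -0.018, camera adjusted p = 0.631).

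The TGF-beta signalling list did not shift either (26 genes, median -0.035, camera adjusted p = 0.425). Tgfb1 differed by 0.16 (95% interval -0.0085 to 0.33, limma adjusted p = 0.370), Tgfb2 by 0.013 (-0.14 to 0.16, adjusted p = 0.948) and Tgfb3 by 0.0092 (-0.27 to 0.29, adjusted p = 0.982), and the signs of Tgfb2 and Tgfb3 turned with some arrays left out. Thbs1 (-0.49), whose product activates latent TGF-beta, was lower adjusted over the list alone, and Smad4 (0.19), Tgfbr3 (-0.18) and Tgfbi (-0.19) did not pass. Of 34 extracellular matrix genes Lama1 rose and Dcn fell over all genes. Adjusted over the list alone 5 were higher, Lama1, Tnc (0.38), Lum (0.37), Col2a1 (0.34) and Col4a2 (0.26), and 3 lower, Dcn, Bgn (-0.43) and Sparc (-0.24), with a camera adjusted p of 0.996. A dimmer row of Bgn differed by -0.052, and the mean of its rows by -0.24. In the list for epithelial-to-mesenchymal transition and cushion mesenchyme, the cadherin gene Cdh11 fell 1.45-fold (limma adjusted p = 0.0395), and Mmp14 (-0.25), Snai1 (0.17) and Itgb1 (-0.18) did not pass (23 genes, median -0.015, camera adjusted p = 0.425). The BMP list (24 genes, median -0.037, camera adjusted p = 0.618) had 0 genes past either threshold, with Acvr1 (-0.23), Bmp10 (-0.23), Bmpr1b (-0.25) and Bmp6 (0.22) at the smallest p-values. So had the FGF list (21 genes, median 0.05, adjusted p = 0.276 with camera; Il17rd -0.27, Etv1 -0.21) and the Wnt list (28 genes, median 0.028, adjusted p = 0.884 with camera; Dkk3 -0.26, Sfrp2 0.29). A dimmer row of Sfrp2 differed by -0.26, with the opposite sign, and the mean of its rows by 0.017.

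Metabolic genes went both ways. In the oxidative phosphorylation list Cox7a1 rose 1.68-fold and Ndufa4 1.43-fold (limma adjusted p = 0.0209 and 0.0300). Adjusted over the list alone 5 were higher, the others being Ndufa1 (0.51), Cox4i1 (0.45) and Cox5b (0.35), and Cox6a2 (-0.22) was lower, and the list was not shifted (23 genes, median 0.035, camera adjusted p = 0.410). In the fatty acid metabolism and PPAR target list Cpt1a, which controls fatty acid entry into mitochondria, fell by 0.58 on the log2 scale (limma adjusted p = 0.0427, 0.0542 with arrays centred on their medians, range over all settings 0.00587 to 0.197). Adjusted over the list alone Cpt1a, Hadhb (-0.42), Lpl (-0.38) and Acadm (-0.30) were lower and Fasn (0.34), for fatty acid synthesis, was higher (28 genes, median -0.099, camera adjusted p = 0.261). The glycolysis and hypoxia list had 0 genes past either threshold, with Vegfa (-0.25), Egln3 (0.40), Slc2a3 (0.26) and Hk2 (0.17) at the smallest p-values (24 genes, median -0.012, camera adjusted p = 0.719). Dlk1 rose 1.59-fold in the imprinted growth list (limma adjusted p = 0.0394), which was not shifted (14 genes, median -0.033, camera adjusted p = 0.957).

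Cell cycle genes (31 genes, median -0.038, camera adjusted p = 0.410; Mki67 -0.23, Ccna2 -0.21) and the list of cell cycle inhibitor, p53 target and apoptosis genes (22 genes, median -0.024, camera adjusted p = 0.425; Bcl2 0.28 and -0.11 for a dimmer row, Ccng1 -0.27) had 0 genes past either threshold. Cdkn1a differed by -0.26 (95% interval -0.49 to -0.03, limma adjusted p = 0.289). The same held for Hox genes (25 genes, 22 above 0, median 0.10, camera adjusted p = 0.0885; Hoxd1 0.36), immediate-early and heat-shock genes (20 genes, median 0.11, camera adjusted p = 0.0885; Btg2 -0.27) and unfolded protein and integrated stress response genes (21 genes, median -0.026, camera adjusted p = 0.884; Vldlr -0.34).

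Among cell type markers, the endothelial and endocardial list was centred near 0 (24 genes, median 0.0061, camera adjusted p = 0.957), with Egfl7 (-0.19), Flt1 (0.16), Tek (-0.17) and Cldn5 (0.17) at the smallest p-values and 0 genes past either threshold. Smooth muscle genes (15 genes, median 0.036, camera adjusted p = 0.386) had Tagln (0.29) higher over the list alone. Erythroid markers (14 genes, median -0.032, camera adjusted p = 0.555) had Rhag (-0.58) lower over the list alone, and Hbb-bh1 (0.28), an embryonic globin, did not pass. Of the macrophage and megakaryocyte markers (17 genes, median 0.024, camera adjusted p = 0.631) Lyz2 (0.38) was higher and Itga2b (-0.33) lower over the list alone. Neural crest markers (15 genes, median 0.10, camera adjusted p = 0.276; Tfap2b 0.41), neural markers (16 genes, median 0.07, camera adjusted p = 0.405; Tubb3 0.23) and head and skeletal muscle progenitor markers (10 genes, median 0.049, camera adjusted p = 0.555; Lhx2 0.39) had 0 genes past either threshold. Xist differed by -0.10 and the Y-linked genes Eif2s3y, Uty and Kdm5d by -0.23, -0.16 and -0.06, with 0 past either threshold (4 genes, camera adjusted p = 0.249). A difference in sex makeup would move Xist and the Y-linked genes in opposite directions. The camera test of the joint list therefore cannot decide whether the pools differed by sex. The single genes did not pass, which at this precision does not show equal makeup.

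Over the 33 lists, the median, the mean and the direction of the camera test differed in sign for 6: glycolysis and hypoxia, Wnt signalling, retinoic acid pathway, imprinted growth, second heart field progenitor and extracellular matrix genes. The estimated-correlation test gave camera adjusted p-values between 0.0988 and 0.997 for all lists, and fry, which tests whether the members of a list move on balance one way, passed 5 lists, namely the 4 above and the sarcomere genes. In the 15 lists with 0 members past either threshold, 0 to 8 members had an unadjusted limma p under 0.05.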

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

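The test against other splits of the arrays was chosen only after its result was seen. Among array rows outside the comparison, those with no gene symbol or several, 13 of 17824 passed an adjusted p of 0.05 in a limma fit over all rows, where 31 rows passed in total. Of the 13, 11 were higher and 2 lower in Hdac3-Isl1KO, and 11 had no listed symbol and 2 had several. These rows were used in no comparison and are unnamed here, and they did not pass more often than the array as a whole.

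The size of the main result was set against other splits of the arrays. Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes as the real split, namely the real split itself with 95 genes in limma, and the highest count of any other split was 0. With 10 splits the share cannot fall below 0.1, too few for a share under 0.05.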

How the results depend on the processing

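The test of protein-coding genes only was chosen after seeing the data. Gene counts (95 by limma) depended strongly on the settings. They were 149 under quantile normalization, 617 and 235 without genes below the median or the 25th percentile row, 866 with a trended prior, plain or robust, 243 with array weights, 317 at an adjusted p under 0.1 and 190 at an unadjusted p under 0.05 with at least 1.5-fold, and 2 to 25 with 1 array left out, where fewer samples were fitted. The share of higher genes was 53.7% among the 95, 42.3% above the median row and 41.0% with the trended prior. The cause of these differences was not tested. Within 1.5 times of 95 were 79 with centred arrays, 82 with the mean of a gene's rows, 66 with at least 1.5-fold and 75 for protein-coding genes only. The 95 genes kept their sign in every refit, as far as they were in it (91 above the median row, 74 protein-coding). Hdac3 stayed lower throughout, at -0.47 in most settings, -0.46 with array weights and -0.52 to -0.43 with 1 array left out. It passed the threshold in limma (adjusted p = 0.00108 to 0.0419) without genes below either percentile row, with both trended priors and with array weights, and over all settings its adjusted p reached 0.244. Of 4 lists shifted by camera, 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, 3 passed on ranks, 5 with fry and 4 to 6 otherwise. Signs turned for Isl1 under quantile normalization (0.026) and, with 1 array left out, for Isl1 (-0.095 to 0.058), Tgfb2 (-0.0036 to 0.036), Tgfb3 (-0.11 to 0.076) and Kdm5d (-0.18 to 0.049). Whether replicate numbers mark a shared litter or day is not given in the sources used here. Same-numbered arrays' deviations from their group means correlated at -0.013, -0.086 and 0.040, and only Hdac3-Isl1KO replicate 3 matched its own number best. Pairing by number was therefore not seen, but so few pairs cannot exclude it. With the replicate block limma called 0 genes (smallest adjusted p = 0.0520), with 2744 at an unadjusted p under 0.05, while the same 4 lists were shifted. Signal over background was not known, so small or absent differences of dim genes are not shown to be absent.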

Other observations

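The lists of small RNA, ribosomal protein, trophoblast, parietal endoderm and decidual genes, and the tests of trophoblast tissue, decidua, an extraction size limit in both ranges of span and the C/D and H/ACA box classes, were chosen after the changed genes were seen. The ribosomal protein genes were shifted up as a list in the Hdac3-Isl1KO hearts. Of 65 measured, 5 rose over all genes and 0 fell, and 25 were higher adjusted over the list alone. Of the 65, 55 had positive differences, with a median of 0.22 (camera p = 3.04e-15, and p = 0.0120 with an estimated correlation), and the median stayed between 0.20 and 0.25 with any 1 array left out and under both other scalings. Rpl9 (0.95), Rps28 (0.57), Rps19 (0.56), Rps24 (0.54) and Rps12 (0.45) were the 5 that rose in limma. Dimmer rows differed by -0.078 for Rps28, -0.090 for Rpl9 and 0.16 for Rps19, by 0.48 and 0.51 for Rps24, and by 0.48 to 0.54 for Rps12. Many ribosomal protein genes have pseudogenes that probes can read in common. Log2 differences also fell with gene span across the 18964 protein-coding genes (Spearman's rho of -0.139 across genes, which are not independent replicates).

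Of 11 trophoblast genes picked because their values were seen to be higher, which is not independent evidence, 7 rose over all genes, the other 4 were higher only when adjusted over the list alone, and the median was 1.22. Of 20 parietal endoderm and Reichert's membrane genes Lama1 alone rose, and the list was not shifted (median 0.028, camera p = 0.196, and p = 0.313 with an estimated correlation). Of 19 decidual markers, 17 were above 0 with a median of 0.046 (camera p = 0.0383, and p = 0.0876 with an estimated correlation). Tdo2 rose, while Prl8a2 and Gja1 fell, and Cited2 (0.35) and Bmp8a (0.28) were also higher over the list alone.

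The higher placental hormone and steroid synthesis genes may come from trophoblast tissue carried into the Hdac3-Isl1KO pools, a hypothesis for which the needed shift was found: 37 other trophoblast markers had a median of 0.0932 with 30 above 0 (camera p = 0.000158, and p = 0.0272 with an estimated correlation), and the 28 of them with no value looked at before the list was written a median of 0.0959 with 23 above 0 (camera p = 0.000172, and p = 0.0133 with an estimated correlation). Any upward shift would have met that need, and this one is far smaller than the pattern. Over all genes 0 of the 37 passed, and over the list alone 4 were higher, Krt8, Krt18, Peg10 and Sct. Of the 37, 4 are also in the epithelial, epicardial or fatty acid lists. The other 33 had a median of 0.0761 (camera p = 0.00276, and p = 0.0443 with an estimated correlation). Krt8 and Krt18 are in the epithelial list and also among the 28. The 28 are therefore not separate from that list, and a wider rise of epithelial genes cannot be told apart. In Hdac3-flox/flox hearts 16 of the 37 stood at or above the median row. The highest readings, which do not rank transcripts across probe sets, were Slc16a3 (9.36 and 9.42 in Hdac3-flox/flox and Hdac3-Isl1KO), Krt18 (8.35 and 8.74) and Peg10 (8.24 and 8.65). Tpbpa of the spongiotrophoblast stayed at 4.31 and 4.41. Yolk sac or hepatic endoderm carried along would need higher endoderm markers, and Afp, Ttr and Apoa1 were higher by 0.462 on average (SE 0.0607). Of these, Afp passed only when adjusted over the endoderm list alone, and Ttr and Apoa1 passed neither threshold. In Hdac3-flox/flox 7 of that list's 18 genes stood at or above the median row, while Apoe, with the highest reading of that list, stood at 8.10 and 8.19. Whether such tissue supplied any of the placental hormone and steroid synthesis transcripts was not tested. For uterine decidua the values oppose each other, with Prl8a2 at -0.841 and the decidual list above 0 by a median of only 0.046 (camera p = 0.0383, but p = 0.0876 with an estimated correlation), so it cannot be told apart, and 11 of its 19 genes read at or above the median row in Hdac3-flox/flox, the highest being Cryab (11.26 and 11.28) and Cited2 (10.91 and 11.26). An effect of the genotype on these genes within heart cells was not tested and stays open.

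The small nucleolar RNA genes with Snora or Snord symbols were lower as a group, with 67 of 73 below 0, a median of -0.41 (-0.38 for the 80 genes of that type in the RefSeq table) and 45 lower over the list alone (camera p = 6.79e-30, and p = 0.0333 with an estimated correlation), and the median was -0.31 without Hdac3-flox/flox replicate 2. The RNA of the genes that contain them was not lower as a group. Its median was 0.00411 for 59 pairs over 45 hosts against -0.37 for their small nucleolar RNAs. The paired difference was 0.431 (SE 0.0631 over pairs, which share pools and some hosts). These values argue against a matching fall of host RNA, but transcription itself was not measured. The shortest 10% of protein-coding genes had a median of 0.0362 (SE 0.0062 over genes), so a general fall of short protein-coding genes was not seen. Their spans ran up to 1942 bases, so they cannot speak for RNAs as short as small nucleolar RNAs. Among genes annotated with spans of 101 to 150 bases, 5 other short RNA genes had a median of 0.146 against -0.23 for 20 small nucleolar RNA genes. The difference was 0.374 (SE 0.0895 over genes, which were read in the same pools). These 5 genes only just reach a minimum that was set after the counts were seen. Loss of RNA below a size limit in extraction is therefore argued against only weakly in that range. At 100 bases or fewer, 47 small nucleolar RNA genes had a median of -0.63. There, loss below a size limit cannot be told apart and may account for part of the fall. Only 3 other short RNA genes were measured, fewer than a minimum of 5 set after these counts were seen (median 0.154, from -0.24 to 0.24, difference 0.781, SE 0.198). All 3 have Scarna symbols and the type guide RNA, so they are close in kind to small nucleolar RNAs. Shorter small nucleolar RNA genes were lower (Spearman's rho of 0.512 with span across genes, which are not independent replicates). So were C/D box genes (47 genes, median -0.64) against H/ACA box genes (26 genes, median -0.20). An effect of the genotype was not tested and stays open.

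The lower proepicardial genes may reflect a smaller share of proepicardial and epicardial cells in the Hdac3-Isl1KO pools, through dissection or through genotype. The 12 markers other than Upk3b, Upk1b and Aldh1a1, which were seen first, had a median of -0.0917 with 8 below 0 (camera p = 0.123, and p = 0.330 with an estimated correlation), so a smaller share of cells and lower expression per cell cannot be told apart with so few markers. The 4 of these with the highest readings differed by between -0.19 and 0.0014, with Gpc3 at 10.77 and 10.72 in Hdac3-flox/flox and Hdac3-Isl1KO, Tbx18 at 8.93 and 8.74, Wt1 at 8.08 and 8.08 and Tcf21 at 7.77 and 7.58, of which 0 passed with limma and 0 had an unadjusted p under 0.05, and these readings decide nothing between the explanations. A biological effect of Hdac3 loss on these genes was not tested separately.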
